A study of Drosophila melanogaster with 12 samples.

How the data were processed

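GFP-positive progenitors of adult female midguts were sorted from mated flies 3 to 4 days old that were then held at 29 °C for 7 days, and 3′ mRNA libraries were sequenced from single ends, per the labels' protocols. The 12 libraries fall into 4 groups by genotype and feed, with 3 libraries in each, and groups and replicate numbers were taken from the sample titles. The submitters' processing notes name the dm6 genome build and bcl2fastq, HISAT2, Bowtie2, DESeq, DESeq2, edgeR and limma without versions or roles. The counter, the gene annotation, the use of strand and the tool that scaled the values are not given in the sources used here.

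The deposited values are whole numbers for 17617 genes in each library, treated as a score: the values themselves show that the authors multiplied each library's read counts by one factor and rounded the products. Low values had gaps or doubled classes at the spacing such a factor leaves, and the best factor per library lay between 0.826 and 1.33, clear in 11 of 12 libraries and not distinguishable from 1 in trxRNAi DSS replicate 1. The factor search, tested on simulated data, found 6 of 6 factors within 0.002. Factors imply between 4432656 and 7228049 reads per library, an estimate that was used only in an alternative. Value totals ranged from 5362337 to 6520981. Scaling libraries in this way sets typical genes level between libraries, so a change in total RNA cannot be measured.

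The design fixed before the data were examined assumed raw counts and a count test. Since the values are scaled, that test was not run. The limma test (limma 3.58.1, statmod 1.5.0, R 4.3.3), the pseudocount of 2 and the filter were chosen after the scaling was seen. Genes with a value of at least 10 in at least 3 libraries were tested, 8399 in all, of which 7870 were protein coding and 177 were snoRNA genes. Values were taken as log2 (value + 2), which understates changes of low genes, and all 12 libraries entered one linear model with a mean per group. Contrasts were tested with moderated statistics with an intensity trend and robust variance, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Standard errors, 95% confidence intervals and p-values are those of that model, with its moderated degrees of freedom. Tested on simulated data with 100 genes changed per fold size, it recovered between 11 and 53% of genes changed 2-fold and between 63 and 92% of those changed 4-fold in 5 comparisons. The lowest shares were those of the interaction, and between 4 and 12 other genes were called. The changed genes were drawn only from genes with higher means than the filter requires, so recovery of the lowest genes was not measured.

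Gene symbols, positions and biotypes came from an Ensembl annotation of the same assembly, and 17520 of the 17617 identifiers matched a symbol while 97 did not. The progenitor marker escargot was not analysed here. The 27 gene lists were fixed before the data were examined: EE peptide hormones, EE fate factors, secretory granule, progenitor markers, Notch targets, enterocyte (EC) markers, digestive enzymes, mitosis, S phase, JAK/STAT, EGFR/MAPK, JNK and wound response, oxidative stress and detoxification, antimicrobial and PGRP, heat shock and unfolded protein response, Trithorax group and COMPASS, Polycomb group, Hox genes, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, proteasome, visceral muscle, hemocytes, trachea, fat body and ovary, and neurons. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation. The planned set test fry, which asks whether a list moved at all rather than more than other genes, was run beside them. The Hox list, with lab as its 1 tested member, and the fat body and ovary list, with 2, were not tested as lists.

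Named genes followed a rule fixed before the data were examined. It took trx and Ptx1 always. It took the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between libraries, with 5 and 5 for the feed effect in trxRNAi and for the interaction, where overlap was allowed. It also took up to 4 members per list with the smallest p. A first draft left out list members taken by the rule, mostly those whose calls ended under an alternative, and they were then added to each comparison, although not every gene the rule took is named. Where several left-out libraries ended such a call, the one with the highest adjusted p is given.

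Alternatives fixed before the data were examined were median-of-ratios rescaling, no filter beyond a value of at least 1 in the 12 libraries, a filter of 5 CPM in 3 libraries, a replicate block, leaving out each library in turn, an absolute log2 difference of at least 1, an estimated correlation, and only the 6 libraries compared. Alternatives chosen after seeing the data were voom without trimmed-mean scaling, voom on values divided by each library's factor, rescaling each library to the mean total, pseudocounts of 0.5 and 8, protein-coding genes alone, and the digestive enzyme level as a covariate. The planned DESeq2 Wald test and voom with trimmed-mean scaling were not run because the values are not raw counts. Overlaps of called genes were tested with Fisher's exact test.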

Results

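Progenitor cells of the adult female Drosophila midgut were sorted by their green fluorescent protein, and their RNA was sequenced from the 3′ ends of transcripts. The cells carried either an RNA interference construct against trithorax (trx), which encodes a histone methyltransferase, or no such construct (control, the driver line crossed to a wild-type stock). Flies were kept at 29 °C for 7 days and received 5% sucrose or 3% dextran sulfate sodium (DSS), a polymer that damages the gut lining, for the last 48 h. The 4 groups of control and trxRNAi flies under the 2 feeds held 3 libraries each. The deposited value totals ranged from 5362337 to 6520981 per library, and between 10147 and 11213 genes had a value above 0. Folds below are those of value plus 2 from the model, not ratios of the printed means. Values are these scaled values as mean ± SD (n = 3), and differences are log2 differences of value plus 2 with their standard error (SE) and the Benjamini-Hochberg adjusted p of the limma test over 8399 genes. The labels did not say whether replicates came from separate flies, so p-values measured the spread between these samples only.

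The RNAi target trx (FBgn0003862, chromosome 3R, 14263358 to 14286903 in dm6 coordinates) had values of 1114, 1217 and 1313 in the control libraries under sucrose and 668, 667 and 448 in the trxRNAi libraries under sucrose. It fell by 1.05 ± 0.19 (SE) there, with an adjusted p of 0.00356. Under DSS, trx had values of 841, 1041 and 652 in libraries labelled control and 715, 758 and 808 in libraries labelled trxRNAi. That difference of -0.13 ± 0.19 did not pass the test (adjusted p = 0.772), its 95% confidence interval ran from -0.53 to 0.28, and it was 0.036 without control DSS replicate 2. The target therefore did not bear out the genotype labels under DSS, and groups are named here only as labelled. The position of the hairpin target relative to the 3′ tags was not given in the sources used here. Ptx1, the paired-like homeobox gene named in the series title (FBgn0020912, chromosome 3R, 30912754 to 30930682), stood at 185 ± 29.1 in control sucrose, 53.7 ± 22.7 in control DSS, 11.7 ± 4.16 in trxRNAi sucrose and 111 ± 31.7 in trxRNAi DSS.

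**Figure D1:**
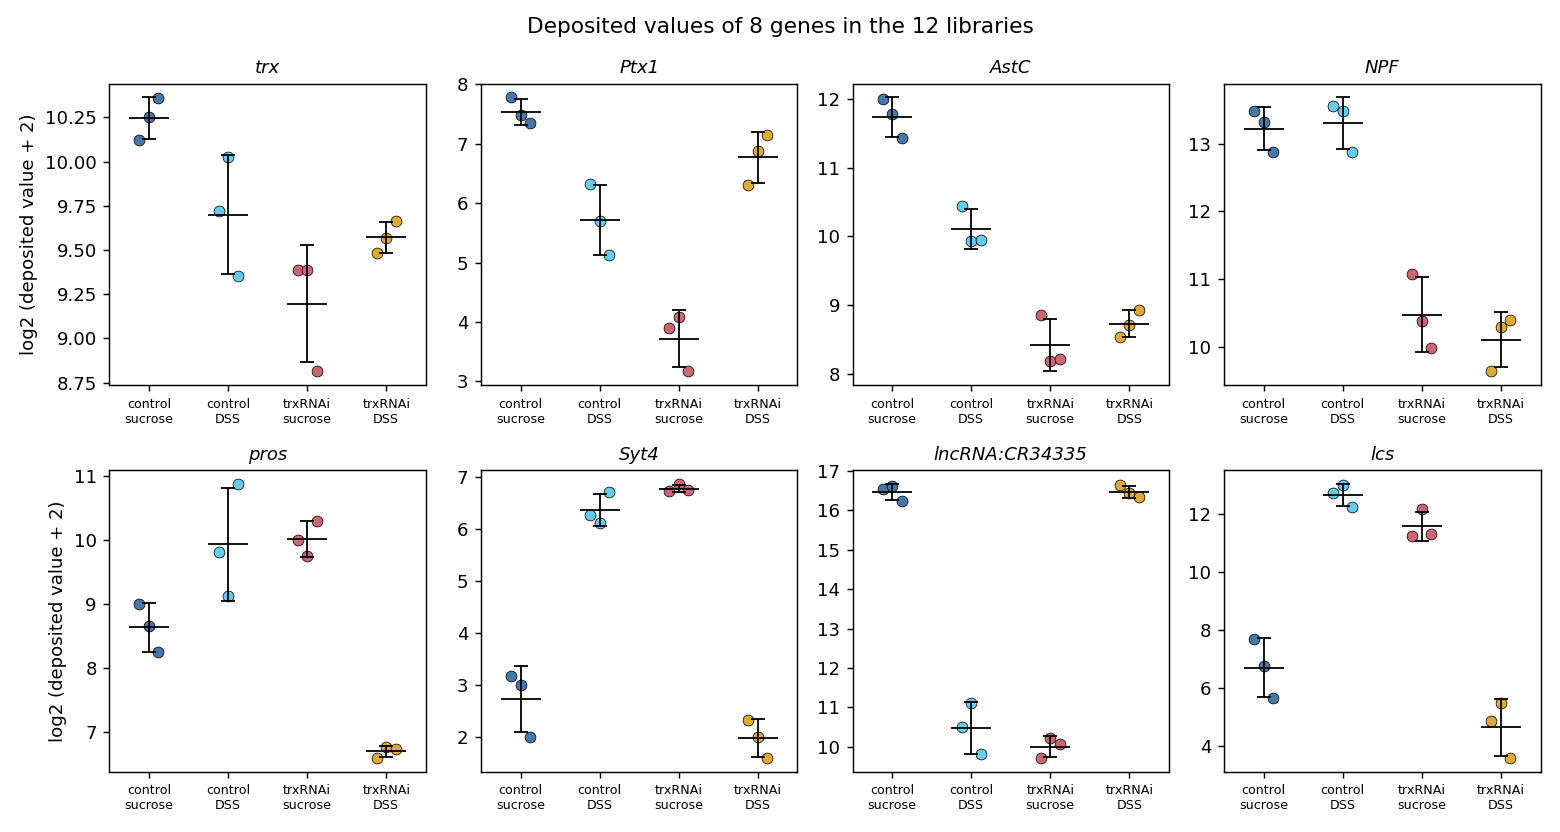
Deposited values of 8 genes on a log2 (value + 2) axis, with each point a library, horizontal bars the group means and whiskers the SD of the 3 libraries. lncRNA:CR34335 had means of 90854 in control sucrose and 91546 in trxRNAi DSS against 1516 in control DSS and 1034 in trxRNAi sucrose, while NPF was lower in both trxRNAi groups.

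The first comparison asked what trx knockdown changed in progenitors of sucrose-fed flies, the homeostatic condition. Libraries labelled trxRNAi held far less RNA of several enteroendocrine (EE) peptide hormones than control libraries. AstC went from 3445 ± 666 to 350.3 ± 99.3, a 9.90-fold fall (adjusted p = 5.89e-08), and Orcokinin from 4618 ± 1041 to 346 ± 92.4, a 13.4-fold fall. NPF fell by 2.75 ± 0.29 on the log2 scale and AstA (-2.13 ± 0.33). Ptx1 fell by 3.82 ± 0.33, or 14.1-fold (adjusted p = 2.71e-06). Of the 10 tested hormones 5 fell and 1 rose, or 6 and 3 adjusted over the list alone. The list was lower by camera, limma's competitive set test (adjusted p = 0.000122), a call lost at an adjusted p = 0.146 with an estimated correlation. Of 17 secretory granule genes, 5 fell and 1 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.00164, and adjusted p = 0.465 with an estimated correlation). Among them the carboxypeptidase gene svr fell by 1.25 ± 0.16, 7B2, whose product assists a prohormone convertase (-1.59 ± 0.25), and the amidating lyase gene Pal2 (-1.92 ± 0.34). The synaptotagmin gene Syt4 went the other way, from 5.00 ± 2.65 to 108 ± 5.86.

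Several other fate genes rose under sucrose. Of 8 tested EE fate factors 5 rose and 1, Ptx1, fell (5 and 2 adjusted over the list alone). The adaptor gene phyl, which acts in sensory and EE precursors, went from 1.67 ± 0.577 to 62.3 ± 12.1, a rise of 17.5-fold in value plus 2, and the proneural gene ase was listed at 0 in every control sucrose library and at 22, 10 and 16 in trxRNAi sucrose. The list passed camera (adjusted p = 0.0392) but had an adjusted p = 0.36 with an estimated correlation. Of 10 Notch target genes 5 rose and none fell, with the same count adjusted over the list alone. E(spl)mgamma-HLH rose by 1.97 ± 0.30 and E(spl)m8-HLH by 4.32 ± 0.66, both of the Enhancer of split repressor family. Camera gave an adjusted p of 0.0002 for these targets, and an adjusted p = 0.0662 with an estimated correlation. Of 11 progenitor markers only spdo, which acts in asymmetric division, passed, with a rise of 2.25 ± 0.36 (1 adjusted over the list alone).

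Part of the cell-cycle genes rose in trxRNAi under sucrose. Of 25 mitosis genes 5 rose (7 rose and 1 fell adjusted over the list alone), among them tum, a cytokinesis gene, by 1.87 ± 0.31. Of 23 S phase genes 7 rose (10 adjusted over the list alone), among them the replicative helicase gene Mcm6 by 1.26 ± 0.22. Camera adjusted p-values were 2.74e-06 and 4.53e-07, and with an estimated correlation the adjusted p was 0.229 for mitosis and 0.142 for S phase. Of 61 oxidative phosphorylation and 33 proteasome genes none passed singly, with medians of 0.28 and 0.29 and camera adjusted p of 1.73e-06 and 0.000904. With an estimated correlation those lists had an adjusted p of 0.571 and 0.528. The 83 cytosolic ribosomal protein genes had a median of -0.12 with no gene passing, over all genes or adjusted over the list alone (camera adjusted p = 0.000904, and adjusted p = 0.585 with an estimated correlation). Of 37 digestive enzyme genes 2 fell and 1 rose, also adjusted over the list alone, with a median of -1.03 (camera adjusted p = 0.000529, and adjusted p = 0.585 with an estimated correlation). Digestive enzymes took between 0.0446 and 0.274% of a library's total, and that share varied within groups, with 0.154 ± 0.104% in control sucrose and 0.0886 ± 0.0402% in trxRNAi sucrose.

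Other large single differences were measured under sucrose. The long noncoding RNA lncRNA:CR34335 (FBgn0267910, chromosome X, 3545750 to 3546110, within DIP-alpha on the same strand) went from 90854 ± 12576 to 1034 ± 183, an 88.1-fold fall (adjusted p = 7.66e-09). Large falls were also measured for asRNA:CR45822 (-4.37), which lies antisense to CTCF, and for pyd3 (-4.01), Acbp3 (-3.76), the homeotic gene lab (-3.60), and the allatostatin receptor genes AstA-R1 (-3.51) and AstA-R2 (-3.26). The largest rises were those of CG13947 (5.93), the lysozyme gene LysD (5.37), the pseudogene CR6434 (5.32), CG43680 (5.19), lcs (4.87), CG16826 (4.65), CG34212 (4.59), CG45080 (4.49) and whe (4.48). lncRNA:CR32835 was listed at 0 in all control sucrose libraries and at 58.3 ± 37.2 in trxRNAi sucrose. The strand use of the authors' counting was not given in the sources used here, so reads of asRNA:CR45822 and CTCF, of lncRNA:CR34335 and DIP-alpha, of CG43680 and Sytbeta, of pros and KP78a or KP78b on the opposite strand, and of the lysozyme paralogs LysB and LysD remained uncertain. In the remaining lists, 2 of 13 enterocyte markers fell, including the homeobox gene exex (-1.98 ± 0.32) (5 adjusted over the list alone). The matrix metalloproteinase gene Mmp1 fell by 0.97 ± 0.18 and the scavenger receptor gene crq (-0.78 ± 0.15). These lists did not pass camera under sucrose, with adjusted p of 0.104 for enterocyte markers, 0.159 for JNK and wound response, where Mmp1 stands, and 0.349 for hemocytes, where crq stands. The others had 0.113 for heat shock and for neurons, 0.228 for Trithorax group and COMPASS, 0.402 for antimicrobial, 0.573 for Polycomb group, 0.676 for JAK/STAT and for visceral muscle, 0.724 for EGFR/MAPK, 0.808 for ribosome biogenesis, 0.845 for progenitor markers and for oxidative stress, and 0.986 for trachea. Median, mean and test differed in sign for progenitor markers, ribosome biogenesis, muscle and hemocytes. The fat body and ovary genes apolpp (-1.44, adjusted p = 0.180) and Yp3 (0.10, adjusted p = 0.945) did not pass.

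Further list members taken by the gene rule passed under sucrose: sc (2.22 ± 0.55) among EE fate factors, E(spl)m6-BFM (4-fold higher), E(spl)m7-HLH (2.01 ± 0.42) among Notch targets, Npc2d (-2.51 ± 0.67) among enterocyte markers. Also taken were Jon25Bii (3.41 ± 0.76), Mal-A3 (-2.12 ± 0.53) among digestive enzymes, asp (1.92 ± 0.48), polo (2.52-fold higher) among mitosis genes, Mcm7 (1.36 ± 0.30), PCNA (1.44 ± 0.32), Mcm3 (0.89 ± 0.21) among S phase genes. Others were rl (2.52-fold lower), aos (0.83 ± 0.21) among EGFR/MAPK pathway genes, Trx2 (0.84 ± 0.22) among oxidative stress and detoxification genes, Drsl3 (3.52 ± 0.71) among antimicrobial and PGRP genes. The left-out library that weakened a call most gave these adjusted p-values, and part of the calls ended without other libraries as well. sc had 0.124, E(spl)m7-HLH 0.0568, Mal-A3 0.0973 and Mcm3 0.120 without trxRNAi sucrose replicate 1. Npc2d had 0.143, asp 0.138, polo 0.163, PCNA 0.0872, rl 0.119, aos 0.143 and Trx2 0.152 without control sucrose replicate 2. Jon25Bii had 0.0835 and Mcm7 0.0781 without trxRNAi sucrose replicate 2. For Drsl3 no left-out library ended the call, and voom gave 0.0716. The call of E(spl)m6-BFM held in the alternatives run.

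In all, 393 genes passed under sucrose, 198 higher and 195 lower, with 268 higher and 148 lower when each library was rescaled to the mean total. Between 183 and 231 passed without trxRNAi sucrose replicate 1, 2 or 3 (189, 183 and 231) or control sucrose replicate 2 (210). Leaving out 1 library also ended the calls of the EE fate list (adjusted p = 0.0501, 0.0538 and 0.10 without control replicate 1, trxRNAi replicate 1 and trxRNAi replicate 3), the digestive enzymes (0.122 without control replicate 1) and the ribosomal proteins (0.143 without trxRNAi replicate 3). Single calls ended without control replicate 2 or trxRNAi replicate 2 for CG16826 (adjusted p = 0.0582 and 0.0659), CG34212 (0.0759 and 0.0731), CG45080 (0.115 and 0.121), whe (0.0779 and 0.113) and AstA-R2 (0.0578 and 0.0720), in part also without further libraries, without trxRNAi replicate 1 for ase (0.0562), and with voom for CG13947 (0.221), LysD (0.0684) and lncRNA:CR32835 (0.149). In 23.4% of genes the 3 libraries of each genotype did not overlap, against 10% by chance.

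The second comparison set trxRNAi against control under DSS, the regenerative condition. Many hormones, granule genes and fate factors and part of the Notch targets fell in libraries labelled trxRNAi. Of 10 EE hormones 7 fell (9 adjusted over the list alone). NPF went from 10341 ± 2496 to 1128 ± 293 (9.19-fold, adjusted p = 1.79e-05), Tk from 862 ± 130.2 to 110 ± 42.9 (8.10-fold), AstC fell by 1.38 ± 0.21 and Orcokinin 4.01-fold. Of 17 granule genes 14 fell, with the same count adjusted over the list alone, including the dense core vesicle gene IA-2 (-3.14 ± 0.26), the calcium channel gene cac (7.99-fold), 7B2 (-2.84 ± 0.25) and Syt4 (-4.40 ± 0.40). Of 8 EE fate factors 6 fell, or 7 fell and 1 rose adjusted over the list alone. The EE determinant pros fell by 3.24 ± 0.35, the basic helix-loop-helix gene tap (-3.63 ± 0.37) and the homeobox gene mirr (-2.12 ± 0.31). Ptx1 differed by 1.06 ± 0.33 with an adjusted p of 0.0567. Camera adjusted p was 7.24e-11 for hormones, 1.59e-16 for granule genes and 1.02e-06 for fate factors, and with an estimated correlation the adjusted p was 0.0247, 0.0334 and 0.0247. sNPF was listed at 0 in all 3 trxRNAi DSS libraries and at 30, 8 and 147 in control DSS.

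Of 10 Notch targets 4 fell under DSS (7 adjusted over the list alone), including E(spl)mgamma-HLH (-2.26 ± 0.30) and E(spl)malpha-BFM (-1.06 ± 0.16), with a camera adjusted p of 9.05e-05, and an adjusted p = 0.0247 with an estimated correlation. Of 11 progenitor markers 4 fell (4 adjusted over the list alone). The asymmetric division gene mira fell by 2.16 ± 0.32 and heca (-0.89 ± 0.17) (camera adjusted p = 0.0107, and adjusted p = 0.346 with an estimated correlation). Of 25 mitosis genes 4 fell (4 adjusted over the list alone), including pav (-1.84 ± 0.42), with a camera adjusted p of 2.40e-05 and an adjusted p = 0.203 with an estimated correlation. Of 23 S phase genes 1, the origin recognition gene Orc1, rose (0 adjusted over the list alone, camera adjusted p = 0.0469, and adjusted p = 0.496 with an estimated correlation). Of 3 neuronal genes 2 fell, including fne (-2.27 ± 0.35) (2 adjusted over the list alone, camera adjusted p = 0.00634, and adjusted p = 0.161 with an estimated correlation). Of 9 muscle genes 2 fell, Mef2 and sls, which are also expressed outside muscle (2 adjusted over the list alone, camera adjusted p = 0.0469, and adjusted p = 0.346 with an estimated correlation). With the replicate number as a block, the muscle list had a camera adjusted p of 0.0630. The members of the muscle list other than Tm1, Mef2 and how together took at most 0.00305% of any library.

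Part of the ribosomal protein genes rose in trxRNAi under DSS, 31 of 83 (54 adjusted over the list alone), and 17 when each library was rescaled to the mean total. RpL30 rose by 0.89 ± 0.13 and RpS21 by 1.04 ± 0.16. The list had a median of 0.41, or 0.28 after that rescaling, which brought the median of all genes to -0.13. Ribosomal protein genes took 34.4, 34.6 and 31.4% of the total in the control DSS libraries and 41.6, 38.9 and 40.2% in the trxRNAi DSS libraries, where snoRNA genes also took more (9.35 ± 0.200 against 7.88 ± 0.206%) and lncRNA:CR40469 less (2.23 ± 0.163 against 4.86 ± 2.10%). Whether reads counted for snoRNA genes came from the genes that hold them was not tested. The values of snoRNA:CG43051-a were 401 in control DSS and 244 in trxRNAi DSS, beside 438.33 and 263.67 for CG43051. The ribosomal protein list's camera adjusted p was 1.06e-19, and the adjusted p = 0.167 with an estimated correlation. Of 61 oxidative phosphorylation genes 5 rose (4 adjusted over the list alone), and 1 when each library was rescaled to the mean total. ND-PDSW rose by 0.82 ± 0.17, and the list's median was 0.39, or 0.26 after that rescaling (camera adjusted p = 1.80e-09, and adjusted p = 0.496 with an estimated correlation). Of 37 digestive enzyme genes 1, Amy-d, rose, also adjusted over the list alone, while 1 rose and 2 fell when each library was rescaled to the mean total. The digestive enzyme list's median was -0.71 (camera adjusted p = 0.0329, and adjusted p = 0.794 with an estimated correlation). Their share was 0.153 ± 0.108% in control DSS and 0.0695 ± 0.0143% in trxRNAi DSS. Single genes of lists that did not pass camera included upd2, a ligand of the JAK/STAT pathway, which fell by 2.18 ± 0.39. The peptidoglycan amidase gene PGRP-LB rose by 1.51 ± 0.30, Mmp1 by 1.09 ± 0.18, crq by 1.04 ± 0.15, exex by 1.87 ± 0.32, the homeobox gene cad by 3.10 ± 0.61 and Prosalpha1 by 1.43 ± 0.27. The 13 lists that did not pass had camera adjusted p from 0.294 to 0.909, and median, mean and test differed in sign for JNK, Trithorax group, hemocytes and trachea.

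Beside cad, the largest rises under DSS were those of lncRNA:CR34335 (6.00, from 1516 ± 659 to 91546 ± 9749.6, adjusted p = 1.01e-08), asRNA:CR45822 (4.41), Sp7 (4.34), pyd3 (4.16), AstA-R1 (3.31), CG43646 (2.87), drm (2.87), tRNA:Pro-CGG-2-2 (2.59) and CG30049 (2.55). The largest falls were those of lcs (-8.01), whe (255-fold), CG34212 (-7.92), CG16826 (-7.46), CG45080 (-7.26), CG13947 (-7.19), CG43680 (-6.90), CG33109 (-6.82), LysB (-6.23) and LysD (-6.23). A total of 793 genes passed, 321 higher and 472 lower, with 201 higher and 595 lower when each library was rescaled to the mean total, and in 25.5% of genes the groups did not overlap. Without control DSS replicate 2, adjusted p-values were 0.141 for progenitor markers, 0.426 for S phase, 0.290 for muscle and 0.956 with a turned direction for digestive enzymes, and without trxRNAi DSS replicate 1 they were 0.0643, 0.0512, 0.228 and 0.0643. Leaving out trxRNAi DSS replicate 3 gave 0.226 for digestive enzymes and 0.137 for S phase, control DSS replicate 3 gave 0.0546 for muscle. Without control DSS replicate 1 the adjusted p was 0.0700 for drm, 0.0534 for pav, 0.115 for Orc1 and 0.0658 for Amy-d, without control DSS replicate 2 it was 0.0575 for Mef2 and 0.117 for sls, these calls except that of pav also ended without further libraries, and CG13947 had 0.260 with voom.

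Under DSS the rule also took Delta (-1.31 ± 0.33) among progenitor markers, E(spl)m6-BFM (-1.30 ± 0.38) among Notch targets, Ssk (-1.99 ± 0.53) among enterocyte markers. Also taken were Incenp (-1.17 ± 0.31), borr (-1.52 ± 0.45) among mitosis genes, vn (1.98 ± 0.49), kek1 (-1.29 ± 0.35), sty (-0.78 ± 0.23) among EGFR/MAPK pathway genes, Gadd45 (0.71 ± 0.20) among JNK and wound response genes. Others were GstS1 (-0.71 ± 0.18), Cyp6a17 (-1.09 ± 0.33) among oxidative stress and detoxification genes, PGRP-SC1b (-3.39 ± 0.86) among antimicrobial and PGRP genes, RpS3A (0.68 ± 0.12) among ribosomal protein genes. The last were ATPsynbeta (0.54 ± 0.14), COX7B (0.68 ± 0.18), ATPsynD (0.61 ± 0.18) among oxidative phosphorylation genes, Syn (-2.10 ± 0.56) among neuronal genes. The left-out library that weakened a call most gave these adjusted p-values, and part of the calls ended without other libraries as well. Delta had 0.106, GstS1 0.110, COX7B 0.119 and ATPsynD 0.152 without trxRNAi DSS replicate 1. E(spl)m6-BFM had 0.155, Incenp 0.116, kek1 0.111 and ATPsynbeta 0.0734 without trxRNAi DSS replicate 2. Ssk had 0.126 and Syn 0.0886 without trxRNAi DSS replicate 3. borr had 0.163 and Gadd45 0.166 without control DSS replicate 1. vn had 0.0877 without control DSS replicate 3. sty had 0.173, Cyp6a17 0.186 and PGRP-SC1b 0.0857 without control DSS replicate 2. The call of RpS3A held in the alternatives run.

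**Figure D2:**
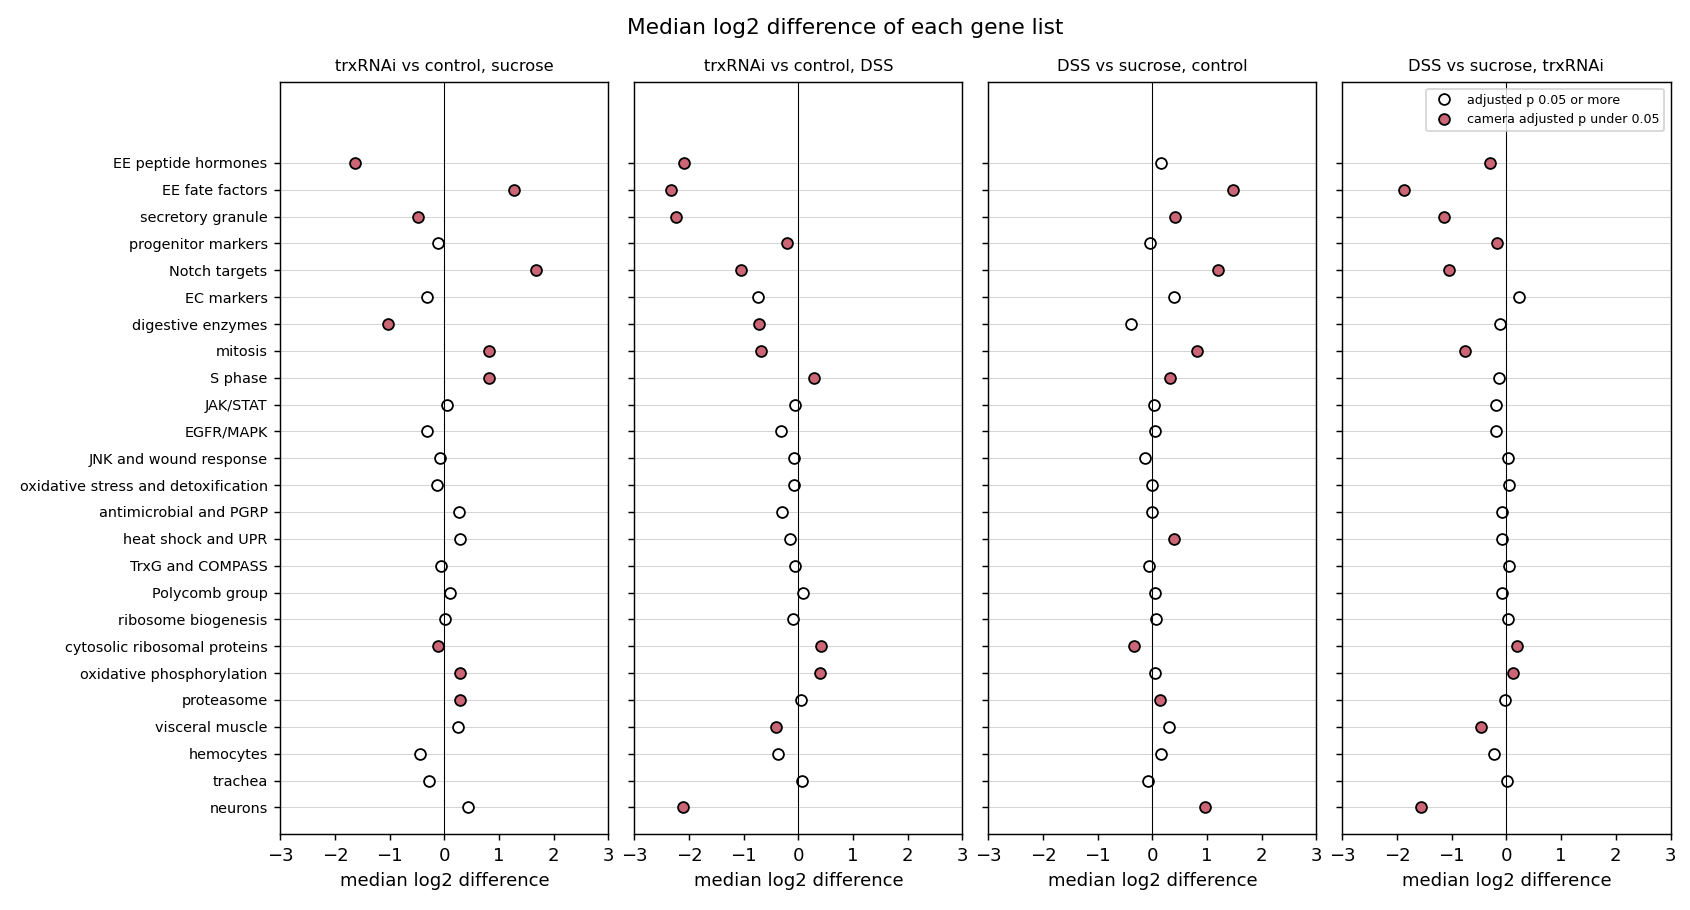
Median log2 difference of the tested members of 25 gene lists in the 4 comparisons, filled where camera gave an adjusted p under 0.05. EE fate factors had medians of 1.28 and -2.33 for trxRNAi against control under sucrose and DSS, and 1.47 and -1.87 for DSS against sucrose in control and trxRNAi.

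The third comparison asked what DSS feeding changed in control progenitors. Part of the fate factors and Notch targets rose, and Ptx1 and AstC fell, in libraries labelled DSS. AstC went from 3445 ± 666 to 1117 ± 233 (3.08-fold, adjusted p = 0.000203), and Ptx1 fell by 1.82 ± 0.33 (3.53-fold, adjusted p = 0.00519). Of 8 EE fate factors 4 rose and Ptx1 fell (6 and 1 adjusted over the list alone), with phyl at 55.7 ± 50.9 under DSS against 1.67 ± 0.577 and a rise of 3.58 ± 0.55. Camera gave an adjusted p of 0.000193, and an adjusted p = 0.122 with an estimated correlation. Of 10 Notch targets 3 rose (5 adjusted over the list alone), E(spl)mgamma-HLH by 1.59 ± 0.30 and E(spl)m8-HLH by 3.53 ± 0.66 among them, and camera gave an adjusted p of 7.04e-05, and an adjusted p = 0.041 with an estimated correlation. Of 17 granule genes Syt4 alone rose, by 3.65 ± 0.40 (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00855, and adjusted p = 0.634 with an estimated correlation). Of 10 EE hormones 2 rose, CCHa2 and sNPF, and 1 fell (2 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.967). CCHa2 stood at 165 ± 20.6 under sucrose and 2010 ± 2071 under DSS.

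Of 25 mitosis genes 2 rose in control under DSS (5 adjusted over the list alone), including tum by 1.76 ± 0.31 (camera adjusted p = 2.89e-07, and adjusted p = 0.211 with an estimated correlation). None of 23 S phase, 24 heat shock and 33 proteasome genes passed singly, over all genes or adjusted over the list alone. Their medians were 0.32, 0.40 and 0.13, their camera adjusted p 0.0192, 0.0192 and 0.0496, and with an estimated correlation their adjusted p was 0.507, 0.727 and 0.842. Of 3 neuronal genes fne rose by 1.94 ± 0.35 (1 adjusted over the list alone, camera adjusted p = 0.0192, and adjusted p = 0.211 with an estimated correlation). Of 83 ribosomal protein genes 8 fell (23 adjusted over the list alone), and 1 when each library was rescaled to the mean total, which brought the median of all genes to 0.15. RpS21 fell by 0.84 ± 0.16, and camera gave an adjusted p of 1.60e-21, and an adjusted p = 0.211 with an estimated correlation. The wound response gene Mmp1 fell by 1.35 ± 0.18, crq (-0.80 ± 0.15) and exex (-2.23 ± 0.32). The other 16 lists had camera adjusted p from 0.0518, for the JNK and wound response list, to 0.979. Signs of median, mean and test differed for progenitor markers, enterocyte markers, EGFR/MAPK, oxidative stress, antimicrobial, Polycomb group and hemocytes.

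The largest rises in control were those of LysD (6.44), CG43680 (6.28), lcs (5.95, from 120.3 ± 79.8 to 6594 ± 1654, adjusted p = 0.000961), CG13947 (5.80), CG34212 (5.74), CG16826 (5.71), whe (5.51), CG45080 (5.33), CG33109 (5.32) and CG44142 (5.29). The largest falls were those of lncRNA:CR34335 (-5.99), asRNA:CR45822 (-4.37), pyd3 (-4.24), Sp7 (-3.49), AstA-R1 (-3.33), CG43646 (-2.99), the trypsin gene zetaTry (-2.96), CG34376 (-2.89), Acbp3 (-2.73) and cad (-2.53). CG34376 lies antisense to Rpn7. In total 259 genes passed, 145 higher and 114 lower (198 and 66 when each library was rescaled to the mean total), and 16.1% of genes did not overlap. The count was 105 with the 6 libraries alone, 133 and 135 without control sucrose replicates 2 and 3, and 139 without control DSS replicate 1. Without control DSS replicate 3 the granule (adjusted p = 0.0851), S phase (0.163), heat shock (0.538), proteasome (0.757) and neuronal (0.146) lists did not pass, without control sucrose replicate 2 S phase (0.0777), heat shock (0.130) and proteasome (0.636) did not. Granule genes had 0.0719 without control sucrose replicate 3, neurons 0.0597 without control sucrose replicate 1 and proteasome 0.0946 without control DSS replicate 1. Without control sucrose replicate 2 the adjusted p was 0.0512 for whe, 0.0850 for CG45080, 0.0880 for zetaTry, 0.128 for cad, 0.0582 for sNPF and 0.137 for CCHa2, each of which also ended without other libraries, while voom gave 0.274 for CG13947 and 0.102 for phyl and the 6 libraries alone 0.0669 for crq.

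In control the rule also took sc (2.23 ± 0.55) among EE fate factors, E(spl)m6-BFM (1.74 ± 0.38) among Notch targets, Jon25Bii (3.21 ± 0.76) among digestive enzymes. Also taken were RpL7 (-0.55 ± 0.13), RpL15 (-0.51 ± 0.12) among ribosomal protein genes. The left-out library that weakened a call most gave these adjusted p-values, and part of the calls ended without other libraries as well. sc had 0.156 and Jon25Bii 0.144 without control sucrose replicate 3. E(spl)m6-BFM had 0.0636 without control DSS replicate 3. RpL7 had 0.105 without control sucrose replicate 2. RpL15 had 0.119 without control DSS replicate 1.

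The fourth comparison repeated the feed contrast in trxRNAi progenitors. Part of the fate factors, granule genes and Notch targets fell, and Ptx1 rose, in libraries labelled DSS. Ptx1 rose 8.30-fold, by 3.05 ± 0.33 (adjusted p = 2.79e-05), while pros fell from 1043 ± 202 to 101 ± 6.43 (-3.32 ± 0.35), and mirr (-1.77 ± 0.31). Of 8 EE fate factors 5 fell and 1 rose (7 and 1 adjusted over the list alone), and camera gave an adjusted p of 4.77e-07, and an adjusted p = 0.0318 with an estimated correlation. Of 10 Notch targets 5 fell (6 adjusted over the list alone), E(spl)mgamma-HLH (-2.64 ± 0.30) and E(spl)m8-HLH (-3.49 ± 0.66) among them, with a camera adjusted p of 1.53e-07, and an adjusted p = 0.00982 with an estimated correlation. Of 17 granule genes 7 fell and 1 rose (12 and 1 adjusted over the list alone), Syt4 (-4.82 ± 0.40) and cac (-1.67 ± 0.27) (camera adjusted p = 4.86e-09, and adjusted p = 0.128 with an estimated correlation). Of 10 EE hormones 3 fell, including Tk (-1.53 ± 0.31) (3 adjusted over the list alone, camera adjusted p = 0.0281, and adjusted p = 0.404 with an estimated correlation). NPF differed by -0.37 and AstC by 0.31, neither passing.

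Of 25 mitosis genes 2 fell in trxRNAi under DSS, ncd and pav (6 adjusted over the list alone, camera adjusted p = 1.53e-07, and adjusted p = 0.128 with an estimated correlation). Of 11 progenitor markers 2 fell, including spdo (-2.23 ± 0.36) (3 adjusted over the list alone, camera adjusted p = 0.0173, and adjusted p = 0.404 with an estimated correlation). Of 3 neuronal genes fne fell by 1.80 ± 0.35 (2 fell adjusted over the list alone, camera adjusted p = 0.00417, and adjusted p = 0.128 with an estimated correlation). Of 9 muscle genes none passed (2 adjusted over the list alone), with a median of -0.46, a camera adjusted p of 0.0172 and an adjusted p = 0.293 with an estimated correlation. Of 83 ribosomal protein genes 1, RpS21, rose (0 adjusted over the list alone and 0 when each library was rescaled to the mean total, camera adjusted p = 6.21e-09, and adjusted p = 0.404 with an estimated correlation). Of 61 oxidative phosphorylation genes none passed in either count, with a median of 0.12, a camera adjusted p of 0.00417 and an adjusted p = 0.833 with an estimated correlation. The homeotic gene lab rose by 2.35 ± 0.43 and crq by 1.02 ± 0.15. The 15 remaining lists had camera adjusted p from 0.217 to 0.984, and those 3 measures differed in sign for oxidative stress, proteasome, hemocytes and trachea.

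The largest rises in trxRNAi were those of lncRNA:CR34335 (6.48), asRNA:CR45822 (4.41), pyd3 (3.92), Sp7 (3.83) and AstA-R1 (3.49), and the largest falls those of CG13947 (-7.32), whe (-6.96), lcs (-6.93), CG34212 (-6.77) and CG45080 (-6.42). In total 298 genes passed, 81 higher and 217 lower, and 21.1% of genes did not overlap. The count was 167 and 194 without trxRNAi sucrose replicates 1 and 2 and 184 without trxRNAi DSS replicate 2. Without trxRNAi DSS replicate 1 the hormones (adjusted p = 0.130), progenitor markers (0.230), oxidative phosphorylation (0.528) and muscle (0.153) lists did not pass, without trxRNAi sucrose replicate 1 hormones (0.134), progenitor markers (0.127) and oxidative phosphorylation (0.127) did not, hormones had 0.0549 without trxRNAi DSS replicate 2. Without trxRNAi sucrose replicate 1 the adjusted p was 0.0847 for ncd, 0.164 for pav and 0.0642 for RpS21, calls that also ended without other libraries, and it was 0.456 for CG13947 and 0.0595 for lab with voom and 0.0775 for CG45080 with the 6 libraries alone.

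In trxRNAi the rule also took Syt1 (-1.64 ± 0.35), nSyb (-1.10 ± 0.24) among secretory granule genes, E(spl)m4-BFM (-2.86 ± 0.61), E(spl)m7-HLH (-1.82 ± 0.42) among Notch targets, GstS1 (-0.69 ± 0.18) among oxidative stress and detoxification genes. The left-out library that weakened a call most gave these adjusted p-values, and part of the calls ended without other libraries as well. Syt1 had 0.0696 and E(spl)m7-HLH 0.113 without trxRNAi DSS replicate 2. nSyb had 0.0782 without trxRNAi sucrose replicate 3. E(spl)m4-BFM had 0.0699 without trxRNAi sucrose replicate 1. GstS1 had 0.219 without trxRNAi DSS replicate 1.

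The feed responses of the 2 genotypes ran in opposite directions. Of 145 genes higher under DSS in control, 100 were lower under DSS in trxRNAi, against 3.75 by chance (Fisher's exact test, p = 1.43e-133), and of 114 lower in control 57 were higher in trxRNAi, against 1.1 by chance (p = 3.10e-94). No gene passed in the same direction in both genotypes, where chance gave 1.40 higher and 2.95 lower. The chance counts and exact p-values in this paragraph treat genes as independent, which they are not. The comparisons set side by side also shared a variance estimate per gene. Across 8399 genes, which are not independent replicates, the feed differences had a Pearson correlation of -0.69 and a Spearman correlation of -0.50. Of the 400 genes called in either genotype 389 had opposite signs. The 157 genes called in opposite directions became 86 with the 6 libraries of each comparison alone, 99 without control sucrose replicate 3 or control DSS replicate 1, and 101 without trxRNAi sucrose replicate 1. The 2 genotype comparisons, which likewise share no library, had 94 genes higher under sucrose and lower under DSS (11.1 by chance, Fisher's exact test, p = 3.44e-66) and 50 the other way round (7.45 by chance, exact p = 2.51e-28), together 94 and 95 without trxRNAi sucrose replicates 1 and 2. Their differences correlated less across genes (Pearson -0.27, Spearman -0.0695), and 616 of the 1004 genes called under either feed had opposite signs. Another 33 were lower under both feeds (11.0 by chance, exact p = 9.11e-09), among them the hormones Orcokinin, AstC and NPF and the granule genes IA-2, 7B2 and Pal2. The 5 higher under both feeds, CG6180, Cht2, LBR, CG6310 and SLC22A, were named after their values were seen and were fewer than the 7.57 of chance (exact p = 0.452). The count lower or higher under both feeds was 38, between 15 and 25 without control sucrose replicate 1 or 2, control DSS replicate 1, or trxRNAi sucrose replicate 1 or 2, and 65 without control DSS replicate 3.

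**Figure D3:**
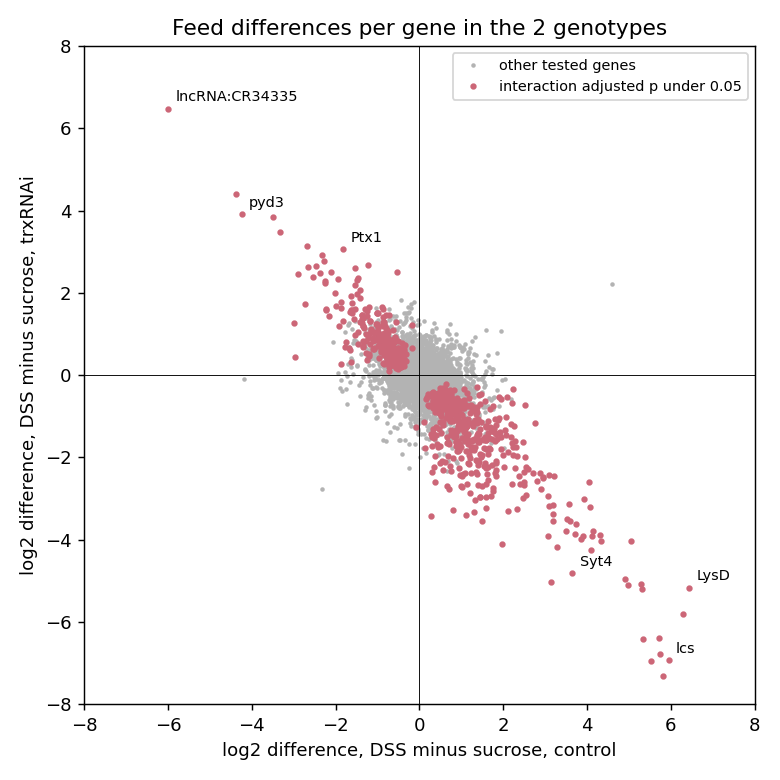
Log2 difference between DSS and sucrose for each of 8399 genes in control (horizontal) and trxRNAi (vertical), with genes of interaction adjusted p under 0.05 in red. Points run from lncRNA:CR34335 at -5.99 and 6.48 to lcs at 5.95 and -6.93, along a falling line.

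Whether the trxRNAi difference depended on the feed was tested as an interaction, and 744 genes passed, 303 positive and 441 negative (167 and 599 when each library was rescaled to the mean total, which brought the median of all genes to -0.23). EE fate factors passed in 8 of 8 cases, 7 negative and Ptx1 positive at 4.87 ± 0.47 (adjusted p = 2.89e-06), with the same counts adjusted over the list alone. Of 17 granule genes 10 were negative and 1 positive, also adjusted over the list alone, with Syt4 at -8.46 ± 0.56 and svr at 1.15 ± 0.23. Of 10 Notch targets 6 were negative (7 adjusted over the list alone), and of 25 mitosis genes 11 (17 adjusted over the list alone), with pav at -3.42 ± 0.59. Of 83 ribosomal protein genes 25 were positive (46 adjusted over the list alone), and 7 after that rescaling. Of 3 neuronal genes fne was negative at -3.75 ± 0.50 (2 adjusted over the list alone). Camera adjusted p was 2.30e-06 for fate factors and 8.62e-07 for Notch targets, with 0.044 and 0.0134 as adjusted p with an estimated correlation. It was 9.41e-07 for granule genes, 6.85e-09 for mitosis, 1.95e-18 for ribosomal proteins and 0.00566 for neurons, with an adjusted p of 0.203, 0.133, 0.203 and 0.173 with an estimated correlation. The hormone list did not pass (adjusted p = 0.343), with AstC at 1.93 ± 0.30 and Tk at -1.88 ± 0.44. The other 18 lists had camera adjusted p from 0.0761 to 0.976, with differing signs for enterocyte markers, EGFR/MAPK, oxidative stress, hemocytes and trachea. For trx itself the interaction was 0.92 ± 0.27 with an adjusted p of 0.0416, a call that ended without control sucrose replicate 2 or 3 (0.0801 and 0.101), control DSS replicate 1 or 3 (0.0778 and 0.0679), trxRNAi sucrose replicate 3 (0.115) or trxRNAi DSS replicate 1, 2 or 3 (0.0565, 0.0841 and 0.10), and after rescaling to the mean total (0.119).

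For the interaction the rule also took nSyb (-1.82 ± 0.33) among secretory granule genes, Delta (-1.96 ± 0.47) among progenitor markers, E(spl)m6-BFM (-3.30 ± 0.54), E(spl)m7-HLH (-3.04 ± 0.59) among Notch targets. Also taken were Ssk (-3.17 ± 0.75) among enterocyte markers, Jon25Bii (-5.65 ± 1.08) among digestive enzymes, Incenp (-1.93 ± 0.44) among mitosis genes. Others were rl (1.99 ± 0.46), aos (-1.21 ± 0.29), vn (2.53 ± 0.69) among EGFR/MAPK pathway genes, GstS1 (-1.30 ± 0.26), Trx2 (-1.23 ± 0.31) among oxidative stress and detoxification genes, esc (-2.54 ± 0.75) among Polycomb group genes. The last were Non1 (1.05 ± 0.28) among ribosome biogenesis genes, RpL7 (0.93 ± 0.18) among ribosomal protein genes, Rpt5 (-0.89 ± 0.27) among proteasome genes. The left-out library that weakened a call most gave these adjusted p-values, and part of the calls ended without other libraries as well. Delta had 0.0714 and vn 0.112 without control DSS replicate 3. Ssk had 0.0653 without trxRNAi DSS replicate 3. Trx2 had 0.0547 without control sucrose replicate 2. esc had 0.113 without trxRNAi DSS replicate 2. Non1 had 0.0701 without trxRNAi sucrose replicate 3. Rpt5 had 0.115 without control sucrose replicate 3. The calls of nSyb, E(spl)m6-BFM, E(spl)m7-HLH, Jon25Bii, Incenp, rl, aos, GstS1 and RpL7 held in the alternatives run.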

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

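The tests of exchanged labels, of enteroendocrine share and of other splits of the libraries were chosen after the result was seen, and the test over chromosome arms was written before it. The trxRNAi difference depended on the feed in 744 genes by the interaction test. The interaction was 0.92 for trx, 4.87 for Ptx1, 12.47 for lncRNA:CR34335, 8.77 for asRNA:CR45822, 8.16 for pyd3, 7.32 for Sp7 and 6.82 for AstA-R1. It was -13.12 for CG13947, -12.88 for lcs, -12.51 for CG34212, -12.47 for whe and -12.11 for CG16826, and 48 other named genes passed as well. List medians of the interaction were -3.64 for EE fate factors, -1.7 for secretory granule, -2.38 for Notch targets, -1.72 for mitosis, 0.49 for cytosolic ribosomal proteins and -2.53 for neurons.

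The pattern behind these results is that feed responses ran in opposite directions in the 2 genotypes. An exchange of genotype labels within sucrose is argued against by trx, whose control minus trxRNAi difference had a lower 95% bound of 0.646. Interaction genes did not gather on one chromosome arm, with 8.11 to 9.62% of genes called per arm. The odds ratio farthest from 1 on a log scale was 0.884. That spread cannot decide on variants carried on one arm, since a variant with the same effect under both feeds cancels in the interaction. An exchange of feed labels within one genotype stays open, and trx cannot decide on it. In both re-paired comparisons trx was lower in trxRNAi, with the higher of the 2 upper 95% bounds at -0.0998. A knockdown would lower trx there under correct labels too, and neither difference passed over all genes (limma, adjusted p = 0.0856 and 0.519). Which genotype would carry the exchange cannot be read from these values. An exchange of genotype labels within DSS cannot be told apart from correct labels by trx, whose lower bound there was -0.277 with 0 inside its interval, but as the whole cause it is argued against by the 315 interaction genes that it would leave, where an exchange of feed labels would leave 0. With the digestive enzyme level as a covariate 807 interaction genes passed, which argues against that level as the whole cause, while a change in gut region or in other cells, and as untested a genotype effect that truly depends on feed, stay open.

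The other pattern is that enteroendocrine genes differed between trxRNAi and control. Under sucrose, 7 of 35 members of the 3 enteroendocrine lists rose and 11 fell. Fate factors gave 5 rises and 1 fall, hormones 1 rise and 5 falls, and granule genes 1 rise and 5 falls. If the feed labels are right, these signs argue against a changed share of enteroendocrine cells of unchanged make-up as the whole cause there. They cannot decide on a change in the mix of such cells, since the lists moved apart. Nor can they decide if feed labels were exchanged within one genotype, which stays open. In trxRNAi sucrose against control DSS, a pairing such an exchange would give, the members of these lists that passed, Ptx1 included, were all lower. Under DSS, 0 rose and 27 fell, so a lower share of such cells could account for the direction, although Ptx1 differed by 1.06, folds ranged widely between members, and the sort for GFP-positive progenitors is meant to leave such cells out. A biological change of fate or of hormone expression in these cells stays open and was not tested.

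For other splits of the same libraries, a comparison of 3 against 3 allows 10 splits, so no share under 0.1 can be had. The real split was the 1 split with as many genes in trxRNAi against control under sucrose (393, highest other 0), in trxRNAi against control under DSS (793, highest other 0), in the feed effect in control (259, highest other 1) and in that in trxRNAi (298, highest other 3). The same held for trxRNAi DSS against control sucrose (151, highest other 0) and trxRNAi sucrose against control DSS (16, highest other 1). For the interaction, 1 of 100 drawn splits of genotype within each feed gave as many genes (744, highest other 315). That other split was the full exchange of genotype within one feed. Such splits assume no genotype effect at all, so they cannot decide on the interaction alone. For the average genotype effect, 2 of 100 did (315, highest other 744), and the higher one points to the structure of the interaction. Neither share excludes chance, since the labels did not say whether replicates came from separate flies.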

How the results depend on the processing

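Of 269 named-gene results, 166 stayed on their side of the threshold in the alternatives run, and of 5113 values 557 lost the call, 5 gained it and 0 reversed. Of 47 called list results 9 stayed in all, and of 919 values 102 lost the call and 3 reversed. The cause of the changes below was not tested, except where fewer libraries or a stricter threshold were used. Requiring an absolute log2 difference of at least 1 left 260 genes under sucrose and 511 under DSS. With only the 6 libraries compared, 105 genes passed for feed in control and 86 were opposite between genotypes. An estimated correlation left 0, 4, 1, 2 and 2 called lists of 10, 12, 9, 10 and 6 in the comparisons sucrose, DSS, feed in control, feed in trxRNAi and interaction. The set test fry, not among the alternatives counted above, called 6, 8, 6, 5 and 7 lists in that order. Under sucrose it passed hormones (adjusted p = 0.00119), fate factors (0.0441), Notch targets, mitosis, S phase and enterocyte markers (0.0311). It did not pass granule (0.197), ribosomal protein (0.303), oxidative phosphorylation (0.255), proteasome (0.197) or digestive enzyme (0.372) genes there. The digestive enzyme covariate, made from that list itself, turned the list's direction under sucrose (adjusted p = 0.977) and DSS (0.944), and left 192 genes for the average genotype effect.

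Leaving out each library in turn gave 183 to 375 genes under sucrose, 531 to 934 under DSS, 133 to 248 for feed in control, 167 to 208 for feed in trxRNAi and 537 to 755 for the interaction. It gave 0 to 5 for the average feed effect (limma, 0 genes with 247 at an unadjusted p under 0.05) and 185 to 627 for the average genotype effect of 315. It gave 6 to 11 called lists for feed in trxRNAi, and an adjusted p of 0.000131 to 0.956 for digestive enzymes under DSS, turned in direction without control DSS replicate 2. Genes called under both feeds ranged from 15 to 65 in the same direction and from 94 to 157 in opposite directions, and those opposite between genotypes from 99 to 146. The trx difference under DSS ranged from -0.30 to 0.036. Rescaling each library to the mean total brought the median of all genes to 0.10 under sucrose and -0.08 for feed in trxRNAi.

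Replicate numbers were not taken as pairs, since only 7 of 18 same-number pairs had r over 0.1 (range -0.20 to 0.276). Yet 10 of 12 libraries correlated best with their own number, a hint from the data of shared structure. These correlations were of residuals from the group means. Mean r was 0.057 for same-number pairs, which largely fixes the -0.028 for other pairs, since residuals cancel within a group. With the replicate number as a block, 458, 865, 299, 311 and 784 genes passed in the same order of comparisons, each above the count without it. The planned DESeq2 test and voom with trimmed-mean scaling were not run. At this depth 2-fold changes were recovered in 11% of simulated genes for the interaction and 46% under sucrose, with the lowest tested genes left out.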

Other observations

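The contrasts in this part were chosen after the data were seen. Averaged over both feeds, 315 genes differed between trxRNAi and control, 95 higher and 220 lower (limma), with 185 to 627 when 1 library was left out and 192 with the digestive enzyme level as a covariate. Those named next, with the smallest adjusted p, were lower in trxRNAi. AstC had an average log2 difference of -2.34 (adjusted p = 1.15e-07), 7B2 of -2.22, NPF of -2.97, the octopamine receptor gene Octalpha2R of -2.61, IA-2 of -2.29, the calcium channel gene Ca-alpha1T of -2.39, Orcokinin of -2.87 and the potassium channel gene Sh of -2.92. The target trx had an average of -0.59 ± 0.14 (adjusted p = 0.0206), which an exchange of feed labels would leave unchanged. Its difference under DSS alone, -0.13, did not pass. Ptx1 had an average of -1.38 (adjusted p = 0.00263), although its difference under DSS was positive. The average feed effect had 0 genes past the threshold.

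Comparing across feeds, trxRNAi sucrose differed from control DSS in 16 genes, 2 higher and 14 lower, and trxRNAi DSS from control sucrose in 151, 23 higher and 128 lower. Leaving out each library in turn gave 5 to 62 genes, the highest without control DSS replicate 3, and 54 to 145 genes. NPF (-2.83), AstC (-1.68), Orcokinin (-2.63), IA-2 (-2.01), 7B2 (-1.70) and Ptx1 were lower in the first of these, and grsm (0.89) and mnd were higher. The mean correlation of libraries across genes was 0.955 between control DSS and trxRNAi sucrose (0.943 to 0.962). It was 0.949 within control DSS (0.930 to 0.964) and 0.968 within trxRNAi sucrose. The control DSS mean was lowered by replicate 3, which stood apart. Its mean chi-square per gene against counting noise was 57.0 and 89.6 beside replicates 1 and 2, which had 22.6 between them. Between control sucrose and trxRNAi DSS the mean correlation was 0.946, against 0.953 within control sucrose and 0.967 within trxRNAi DSS. On the first principal component, with 29.5% of the variance, the control DSS and trxRNAi sucrose libraries lay on one side and the other 6 on the other. The second, with 18.3%, had all trxRNAi libraries from -23.7 to -9.84 and 5 of 6 control libraries from 4.80 to 36.4, with control DSS replicate 3 at -16.6.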
